A study of Mus musculus with 6 samples.

How the data were processed

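RNA from cervical spinal cord of mouse embryos at embryonic day 11.5, without the dorsal cord and the floor plate, was isolated with a column kit for small samples, amplified by whole-transcriptome amplification into sense-strand cDNA, fragmented and labelled with biotin, per the labels' protocols. The samples were 6 arrays, 3 labelled Nkx2.9 knockout and 3 labelled wild type, grouped by the genotype in the labels. The deposited log2 values were made by the authors with RMA (robust multi-array average), per the submitters' processing notes, which background-corrects, normalizes between arrays and summarises probes; its version and settings were not given in the sources used here. The log base was not stated with the values and was taken as 2, the base RMA uses. In the deposited table the median of every complete probe set over the 6 arrays was 0 within 1e-06, so each probe set had been centred on its own median. Neither the expression level nor the signal over background of a probe set could then be seen, while differences between arrays and their p-values are not altered by that centring. The table had 28815 probe sets, of which 24 had no value in wild-type C and were fitted on the remaining 5 arrays.

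Gene symbols came from the annotation of the array platform. Of the probe sets 21780 had 1 symbol, 1605 several and 5430 none, and no gene was named from a probe set with several. Entrez identifiers of 21689 were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used only for names and for the order of neighbouring genes; no coordinates are given because the build of the annotation was not given in the sources used here. For each of 19920 genes 1 complete probe set was used, the one with the most accessions in the annotation, with ties going to the lowest identifier; 998 genes had several. The brightest probe set per gene had been planned, which the centred values did not allow.

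The comparison of the arrays labelled knockout with the wild type used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the only term, Benjamini-Hochberg adjustment over all probe sets and a threshold of adjusted p under 0.05. A count at unadjusted p under 0.01 and at least 1.5-fold was set beside it as a description. Standard errors are those of limma's moderated fit, and SDs are over the 3 arrays of a group. Nkx2-9 was also compared by an exact two-sided permutation test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 30 lists, with camera at an estimated correlation and limma's fry beside it. Of the 31 lists 1 had under 5 measured genes and was not tested. The lists covered Nkx and ventral progenitor transcription factors, floor plate and V3 domain, Hedgehog, Notch, somatic and dorsal-exiting motor neurons, Slit and Robo, netrin and DCC, Eph and ephrin, semaphorins, axonal cell adhesion molecules, metalloproteinases, basal lamina, interneurons, dorsal cord and dorsal root ganglion. They also covered neural crest, mesenchyme, muscle, vessels, erythroid cells, macrophages, neural progenitors, cell cycle, differentiated neurons, anterior and posterior Hox genes, sex-linked genes, neighbours of Nkx2-9, immediate early genes and hypoxia. Some genes stand in several lists. Adjustment over a list alone means Benjamini-Hochberg over its measured members. It was not corrected for the number of lists, so a member can pass in some list by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

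The tests, the gene lists and the alternatives were fixed before the data were examined, apart from those named as added. The genes named were Nkx2-9; in each direction up to 14 genes past the adjusted threshold, filled with those of lowest p among genes at unadjusted p under 0.01 and 1.5-fold; the candidate genes; and, per list, up to 4 members past a threshold or else the 2 of lowest p. Predicted genes, clone names, receptors of smell and small RNAs were counted but not taken among the 14. Alternatives were the letter as a replicate block, quantile normalization, median centring of arrays, array weights, 1 probe set per gene, an unequal-variance test, the mean over the probe sets of a gene, and leaving out each array. Quantile normalization was applied to the centred values, so it gave the deviations of all arrays 1 distribution. It thereby also shrank real differences, such as that of Xist from 3.39 to 2.12. A filter at the 30th percentile of brightness and variance priors with an intensity trend had been planned and were not run, since no level was left in the values. A robust prior without a trend and a term for the 2 arrays with high Xist were added after the data were seen, as were the count of posterior Hox genes and camera at an estimated correlation under each other setting. With the Xist term the genotype difference is read from knockout A against the wild type, and that array is assumed to vary like the other groups.

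The procedure was tested on simulated values for 28791 probe sets with the real spreads: it called 76.1% of 67 probe sets changed 1.5-fold with 9 false calls in all, and 0 with no change simulated, where 16 passed the unadjusted p of 0.01 and 1.5-fold. The noise was drawn independently for each probe set, so differences shared by many genes on an array were not simulated. All changed probe sets were simulated together, which eases the adjustment, so these shares do not hold where only a few change.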

Results

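The series profiled cervical spinal cord of mouse embryos at embryonic day 11.5, with the dorsal part of the cord and the floor plate left out of the tissue, on whole-transcript expression arrays. There were 3 arrays labelled Nkx2.9 knockout and 3 labelled wild type, with the letters A, B and C in each group. Nkx2-9 encodes a homeodomain transcription factor of ventral neural progenitors, and the stated purpose was to find genes acting downstream of it in the development of spinal accessory motor neurons, whose axons leave the cord at a lateral exit point. The deposited table held 28815 probe sets, and 28791 of them had a value on all 6 arrays. Each value was a log2 expression value with the median of that probe set over the 6 arrays subtracted, so differences between arrays could be measured but the expression level of a gene could not. The median of an array's values lay between -0.01 and 0.01. No pair among the 15 pairs of arrays held identical values. The labels did not say whether the arrays came from separate embryos or from pools, so the p-values measured only the spread between these samples, and the number of arrays limited the precision.

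The targeted gene was examined first. Nkx2-9 did not fall in the arrays labelled knockout: its value was 0.10 ± 0.17 there and -0.08 ± 0.14 in the wild type (SD, n = 3 each). The difference of 0.18 on the log2 scale (SE 0.11), 1.14-fold higher in the arrays labelled knockout, was larger than the SD of either group and did not pass a test (adjusted p = 0.812 in limma; exact two-sided permutation p = 0.2, where 3 arrays against 3 can give no less than 0.1). The position of the Nkx2-9 probes relative to the deleted part of the gene was not known, and probes outside that part check nothing about the labels. Nor could the centred values show whether the Nkx2-9 signal stood over background. A transcript that was not detected in either group would check nothing either. The arrays are therefore called labelled knockout throughout, and every direction given below rests on those labels.

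No probe set passed an adjusted p of 0.05 in limma across the whole table. The genes named next had an unadjusted p under 0.01 and at least a 1.5-fold difference; larger differences with a higher p, such as those of sex-linked genes, are given further on. Lower in the arrays labelled knockout were Hoxb9, at a log2 fold change of -0.99 (SE 0.12, 1.98-fold), and Dhrs3, a retinaldehyde reductase, at -0.85 (SE 0.13, 1.80-fold). Hoxa6 (-0.92, SE 0.16), Hoxc6 (-1.29, SE 0.27) and Hoxd8 (-1.19, SE 0.29) were lower as well, as were the diacylglycerol kinase gene Dgkk (-1.01, SE 0.27), Vstm2a (-0.94, SE 0.25), Tmem108 (-0.63, SE 0.11), Lypd1 (-0.63, SE 0.15) and Clvs2 (-0.60, SE 0.11). Higher were Ddc, which encodes aromatic L-amino acid decarboxylase, at 0.63 (SE 0.09, 1.55-fold), the proteoglycan gene Vcan (0.66, SE 0.17), Greb1l (0.65, SE 0.17), the deubiquitinase gene Usp44 (0.62, SE 0.12) and the transcriptional coactivator gene Eya1 (0.61, SE 0.16). Vcan and Eya1 were highest on the array labelled knockout C, at 0.80 and 0.81. Without that array their differences were 0.45 and 0.43, and without the array labelled knockout B 0.74 and 0.76. In each of these 15 genes all 3 arrays labelled knockout lay on one side of all 3 wild-type arrays. The genes were chosen by p and fold change on these same arrays, so that separation is no further support.

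The smallest unadjusted p in limma was 0.000121, for Hoxb9, and its adjusted p was 0.812. No probe set passed with an unequal-variance test per probe set or at an adjusted p of 0.1 either. At an unadjusted p under 0.05 there were 1605 probe sets (5.57% of the table), 886 of them higher and 719 lower in the arrays labelled knockout. The share that was higher, 55.2%, was 50.1% with arrays centred on their medians, and it turned to 48.5% with quantile normalization, 48% without the array labelled knockout B and 44.7% with a term for the 2 arrays with high Xist, the X-inactivation RNA. With an unadjusted p under 0.01 and at least a 1.5-fold difference there were 18, of which 5 were higher and 13 lower. Of these, 16 carried 1 gene symbol and 2 did not. Simulated values with no change gave 16 probe sets at the same thresholds. The groups did not overlap in 3148 of the complete probe sets (10.93%), where chance gives 10%. The count of 18 was 124 without the array labelled knockout B (34 higher, 90 lower) and 9 without wild-type B, all lower. Without wild-type C it was 55 and the direction turned, with 30 higher and 25 lower. With the Xist term 33 were higher and 39 lower, and with quantile normalization 4 and 19. In simulated data of the same size, limma called 76.1% of 67 probe sets changed 1.5-fold, 95.5% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. The simulated noise was independent between probe sets, so differences shared by many genes on an array were left out. The changed probe sets were drawn at random, so the shares are for typical ones (median SD within groups 0.083) and not for more variable genes. All of them were changed together in the same simulated table, and the adjustment is easier to pass when many probe sets change. The shares therefore do not hold where only a few change, and a count of 0 does not exclude such changes. Hoxb9, at 1.98-fold with SDs of 0.18 and 0.17, did not pass.

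Hox genes set the position of neurons along the head-to-tail axis, with higher paralog groups expressed further towards the tail. Of the 17 measured posterior Hox genes (paralog groups 5 to 10), 14 were lower in the arrays labelled knockout, with a median log2 fold change of -0.30. None passed over all probe sets, and 6 passed when adjusted over the list alone in limma: Hoxb9 (adjusted p = 0.00206), Hoxa6 (0.00899), Hoxc6 (0.0161), Hoxa7 (0.0177; log2 fold change -0.40, SE 0.09), Hoxd8 (0.0177) and Hoxa9 (0.0306; -0.35, SE 0.10). Hoxa9 was outside the naming rule and was named after its value was seen. The list was called by camera with the preset correlation (adjusted p = 1.96e-07) and not with an estimated correlation (adjusted p = 0.384). The 11 measured anterior Hox genes (paralog groups 1 to 4) had a median of 0.04, with 6 higher and 5 lower, and no member passed over the list alone (camera adjusted p = 0.96); this median turned to -0.034 without wild-type B and was 0.11 without wild-type A. Hoxd3 was at 0.31 (SE 0.14; 0.17 without wild-type B) and Hoxb1 at -0.21 (SE 0.10). Hoxc8 stood at 3.56 in wild-type B and between -0.47 and 0.27 on the other arrays; its SE was 0.92. Without wild-type B, 3 posterior Hox genes passed over the list alone, and without the array labelled knockout A the median of the list was -0.16.

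**Figure D1:**
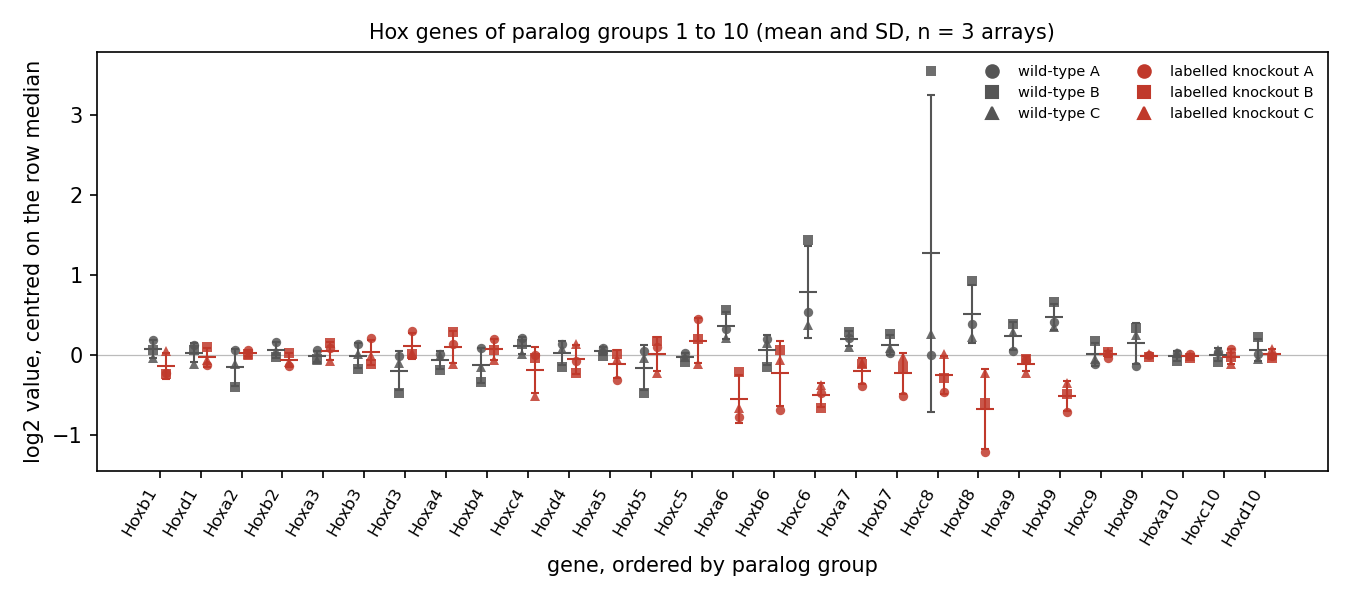
Log2 values, centred on the median of each probe set over the 6 arrays, of the measured Hox genes of paralog groups 1 to 10, with wild-type arrays in grey, arrays labelled knockout in red, and bars giving the mean and SD (n = 3 arrays each). Hoxa6, Hoxc6, Hoxd8 and Hoxb9 have all 3 arrays labelled knockout below all 3 wild-type arrays, the genes of paralog group 10 lie near 0, and Hoxc8 reaches 3.56 in wild-type B.

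Axon guidance and motor neuron genes fixed in advance were compared next, since the study concerned spinal accessory motor neurons. Robo2, a receptor for Slit proteins, had the largest difference of the 13 measured candidates, at -0.72 (SE 0.28, 1.65-fold lower in the arrays labelled knockout). It stood at -0.62, 0.07 and -0.97 in the arrays labelled knockout A, B and C and at -0.07, 0.53 and 0.19 in wild-type A, B and C, so that the groups overlapped. Slit3, a ligand of the same family, was at 0.30 (SE 0.11), Robo1 at -0.20 (SE 0.10) and Alcam, a cell adhesion molecule of motor axons, at -0.32 (SE 0.18). No candidate passed over all probe sets or adjusted over the list alone in limma, where Robo2 and Slit3 had adjusted p = 0.255. The log2 fold changes of the other 9 were -0.24 for Unc5c, 0.20 for Tbx20, 0.15 for Slit2, -0.14 for Dcc, 0.10 for Robo3, 0.09 for Cxcr4, -0.09 for Slit1, -0.04 for Isl1 and 0.03 for Ntn1, with adjusted p over the list alone from 0.43 to 0.832. Without the array labelled knockout B, 3 candidates passed over the list alone, Robo2 at -1.01 (SE 0.20, adjusted p = 0.0191), Robo1 at -0.32 (SE 0.05, adjusted p = 0.0107) and Slit3 at 0.40 (SE 0.10, adjusted p = 0.0368). Without the array labelled knockout C none passed, and Robo2 was at -0.49, Robo1 at -0.13, Slit3 at 0.19 and Alcam at -0.12. Other values rested on single arrays as well: Unc5c was at -0.0044 without wild-type B and -0.45 without wild-type C, Tbx20 at 0.014 without the array labelled knockout A, and Slit2 at 0.0057 without wild-type C and 0.27 without wild-type B. Dcc was at -0.049 and Slit1 at -0.018 without the array labelled knockout C, and Cxcr4 at 0.025 without wild-type B. Robo3 turned to -0.030 without the array labelled knockout A, Ntn1 to -0.078 without knockout B, and Isl1 to 0.048 without knockout B and 0.12 without wild-type B.

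**Figure D2:**
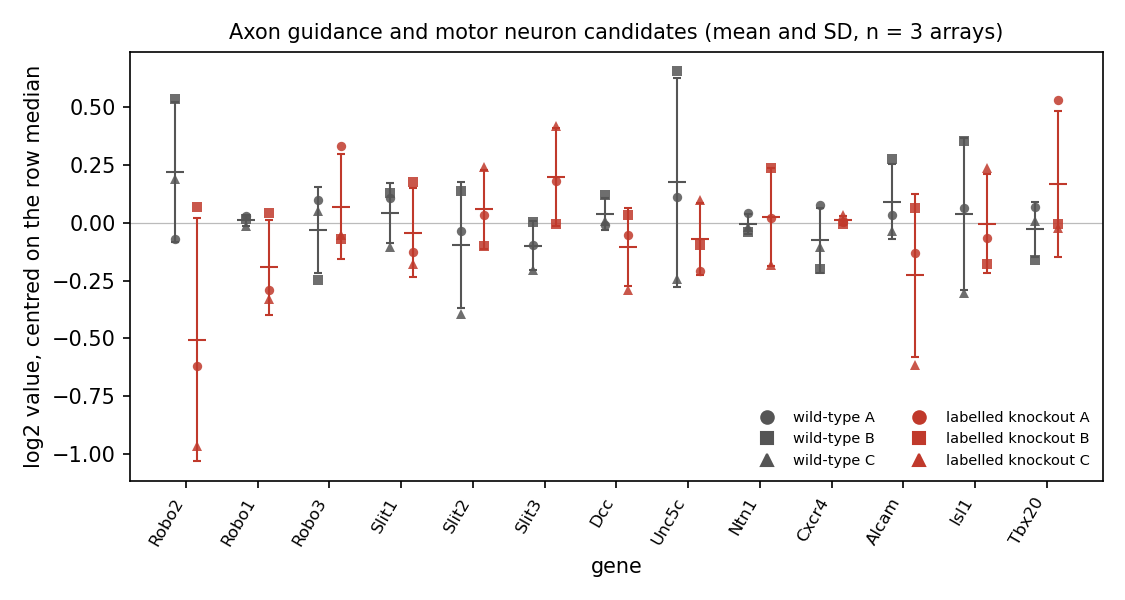
Log2 values, centred on the median of each probe set over the 6 arrays, of the 13 measured candidate genes, with wild-type arrays in grey, arrays labelled knockout in red, and bars giving the mean and SD (n = 3 arrays each). Robo2 lies at -0.62 and -0.97 in the arrays labelled knockout A and C and at 0.07 in B, within the range of the wild type.

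Among the guidance families, the cell adhesion molecules of axons were lower in the arrays labelled knockout. The median over its 35 measured genes was -0.20, and 30 were lower. Camera called the list (adjusted p = 1.47e-07) but not with an estimated correlation (adjusted p = 0.724), and no member passed over the list alone; Cdh22 was at -0.24 (SE 0.07) and Igsf8 at -0.12 (SE 0.04). The median was -0.10 without wild-type B and -0.13 without the array labelled knockout C. Semaphorins, plexins and neuropilins had a median of -0.05 over 31 genes, with 19 lower (camera adjusted p = 0.0491; adjusted p = 0.724 with an estimated correlation), and Sema6d was at -0.30 (SE 0.09) and Sema6c at -0.18 (SE 0.05). This call ended without wild-type A (adjusted p = 0.085), wild-type B (0.221) or the array labelled knockout C (0.199), and also with quantile normalization (0.0722), arrays centred on their medians (0.0534), array weights (0.0629) and the Xist term (0.416). The median was -0.10 without the array labelled knockout B, -0.08 without wild-type C and -0.09 with the Xist term. In the Eph and ephrin list 1 of 21 genes passed over the list alone, Epha2, at 0.25 (SE 0.05, adjusted p = 0.0453), while the list itself was not called (median -0.02, camera adjusted p = 0.734). That pass was not corrected for the number of lists, and over all probe sets Epha2 had adjusted p = 0.812 in limma. Slit and Robo signalling (12 genes, median 0.01, adjusted p = 0.907) and netrin and DCC signalling (14 genes, median -0.03, adjusted p = 0.401; Dscam -0.32, SE 0.17, and Unc5b 0.11, SE 0.06) were not called, and no member passed over either list alone. With single arrays left out the medians of these 3 lists changed sign, within -0.084 and 0.051, and Dscam was at -0.15 without the array labelled knockout C and -0.47 without B, and Unc5b at 0.071 without wild-type B.

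Motor neuron identity genes did not pass as lists with all 6 arrays. Somatic motor neuron genes had a median of -0.07 over 22 genes (camera adjusted p = 0.0605), and the 2 of lowest p were Hoxc6, which the posterior Hox list also holds, and Isl2 at 0.18 (SE 0.07). The somatic list was called without wild-type C (median -0.17, adjusted p = 0.000137) and with array weights (0.0409), but with an estimated correlation in neither (adjusted p = 0.531 and 0.749), and its median was -0.0015 without wild-type B. Genes of dorsal-exiting motor neurons, the branchial and spinal accessory class, had a median of -0.03 over 13 genes (adjusted p = 0.401), with Gata2 at 0.16 (SE 0.05) and Rgs4 at -0.11 (SE 0.04); the median was -0.087 without the array labelled knockout C and 0.016 without B. Ventral and intermediate interneuron genes had a median of -0.09 over 23 genes (adjusted p = 0.0767), with Evx2 at 0.21 (SE 0.07); this list was called without the array labelled knockout B (0.0167) and without wild-type C (0.0324), but with an estimated correlation in neither (adjusted p = 0.668 and 0.531). Its median was -0.040 without the array labelled knockout C (adjusted p = 0.305), -0.052 without knockout A and -0.062 without wild-type B, and Evx2 was at 0.13 without wild-type A.

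Cell cycle genes were higher in the arrays labelled knockout and neuronal genes lower, both in calls that ended with an estimated correlation. All 23 measured cell cycle genes were higher, with a median of 0.33 (camera adjusted p = 1.47e-07; adjusted p = 0.724 with an estimated correlation), but no member had an unadjusted p under 0.05. The replication gene Mcm6 was at 0.39 (SE 0.17) and the mitotic kinase gene Plk1 at 0.34 (SE 0.17). The cell cycle median of wild-type B was -0.56, against -0.11 to 0.26 on the other arrays, and without wild-type B the log2 fold change of the list was 0.12, that of Mcm6 0.24 and that of Plk1 0.16. Differentiated neuron genes had a median of -0.13, with 22 of 25 lower (adjusted p = 5.27e-07; adjusted p = 0.724 with an estimated correlation), among them Syt1 at -0.44 (SE 0.17) and Elavl3 at -0.13 (SE 0.04). That median was -0.07 without wild-type B and also without the array labelled knockout C.

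Patterning and progenitor genes showed small differences. Nkx and ventral progenitor transcription factors had a median of 0.10, with 12 of 17 higher (camera adjusted p = 0.0143; adjusted p = 0.724 with an estimated correlation), including Irx3 at 0.30 (SE 0.09) and Neurog1 at 0.16 (SE 0.06). This call ended without the array labelled knockout C (adjusted p = 0.0787), without wild-type C (0.149) and with the Xist term (0.243). The list is not purely ventral: it holds Pax3 and Pax7, which the dorsal cord list shares, both at -0.02. Nkx2-2 was at -0.09, Olig1 at 0.01 and Olig2 at 0.11, all named after their values were seen. Notch pathway genes had a median of 0.13, with 15 of 18 higher (adjusted p = 0.0105; adjusted p = 0.724 with an estimated correlation); the Notch ligand genes Dll1 and Dll3 were at 0.12 (SE 0.04) and 0.18 (SE 0.06). The Notch median was 0.08 without the array labelled knockout C and 0.08 with the Xist term, and Dll3 was at 0.11 without knockout C. No member of either list passed over its list alone. Floor plate and V3 domain genes (16 genes, median 0.14, adjusted p = 0.114), the Hedgehog pathway (12 genes, median 0.06, adjusted p = 0.601) and neural progenitor genes (18 genes, median 0.05, adjusted p = 0.357) were not called. The floor plate list was called without wild-type A (0.0447) and without the array labelled knockout C (0.0155), but with an estimated correlation in neither (adjusted p = 0.754 and 0.773), and its median was 0.034 without wild-type B. Foxa2, a floor plate transcription factor, was at 0.22 (SE 0.07), Foxa1 at 0.18 (SE 0.05), Gas1 at -0.22 (SE 0.08), Disp1 at 0.13 (SE 0.06), Prom1 at 0.36 (SE 0.13) and Notch1 at 0.34 (SE 0.13). Without wild-type B, Prom1 and Notch1 were both at 0.21 and the medians of the Hedgehog and progenitor lists turned to -0.011 and -0.013; the progenitor median was 0.091 without wild-type A, and Disp1 was at 0.079 without the array labelled knockout C.

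**Figure D3:**
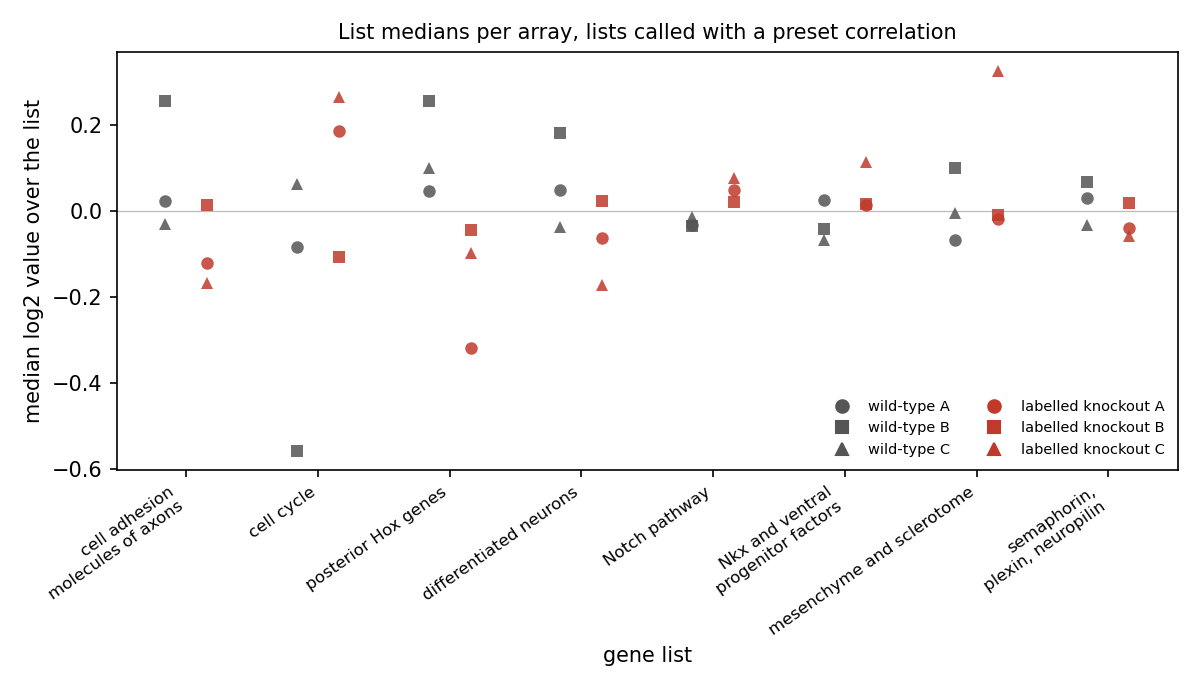
Median log2 value per array over the measured members of the 8 gene lists that camera called with its preset correlation, with wild-type arrays in grey and arrays labelled knockout in red. Wild-type B lies lowest for cell cycle genes, at -0.56, and the array labelled knockout C lies highest for mesenchyme, at 0.33.

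Mesenchyme, vessel and basal lamina genes had their highest medians in the array labelled knockout C. Mesenchyme and sclerotome genes had a median of 0.11, with 24 of 26 higher in the arrays labelled knockout (camera adjusted p = 0.0452; adjusted p = 0.765 with an estimated correlation), and no member had an unadjusted p under 0.05; Sox9 was at -0.11 (SE 0.06) and Prrx2 at 0.10 (SE 0.06). The median on the array labelled knockout C was 0.33, against -0.07 to 0.10 on the other arrays, and without that array the log2 fold change of the list was -0.03 (adjusted p = 0.358). The call also ended without wild-type A (median 0.06, adjusted p = 0.261) or wild-type C (0.131), and with quantile normalization (0.0722), array weights (0.144) and the Xist term (median -0.04, adjusted p = 0.763). The median was 0.17 without the array labelled knockout A and 0.17 without that labelled knockout B. Vessel genes had a median of 0.09 over 18 genes (adjusted p = 0.387; Vtn 0.69, SE 0.34; Erg 0.34, SE 0.19) and stood at 0.34 on the array labelled knockout C. Basal lamina genes had a median of 0.09 over 24 genes (adjusted p = 0.0618; Lama1 0.23, SE 0.08; Fn1 0.32, SE 0.16) and stood at 0.26 on that array. Without the array labelled knockout A both were called (adjusted p = 0.0339 for vessels and 0.00559 for basal lamina), and basal lamina also without wild-type B (0.0216). With an estimated correlation neither was called without knockout A (adjusted p = 0.746 for vessels and 0.693 for basal lamina), nor basal lamina without wild-type B (0.838). Without the array labelled knockout C the vessel median turned to -0.055 (adjusted p = 0.198) and the basal lamina median was 0.018 (0.883), with Erg at 0.12, Fn1 at 0.21 and Sox9 at -0.069. Vtn was at 0.30 and Fn1 at 0.16 without wild-type B, which stood at -1.22 for Vtn, and Prrx2 was at 0.055 without wild-type C.

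The other marker lists were not called by camera with all 6 arrays, and none of their members passed over its list alone. Dorsal spinal cord genes had a median of -0.02 over 28 genes (adjusted p = 0.0767), with Barhl2 at -0.57 (SE 0.11, adjusted p = 0.0589 over the list alone) and Barhl1 at -0.27 (SE 0.09); this list was called without wild-type B (0.00239) and without the array labelled knockout A (0.0339), but with an estimated correlation in neither (adjusted p = 0.838 and 0.693). The dorsal cord median was -0.0025 without the array labelled knockout C, -0.080 without knockout B and 0.011 without wild-type C. Dorsal root ganglion genes had a median of -0.01 over 16 genes (adjusted p = 0.734; Runx3 0.18, SE 0.07; Six4 0.19, SE 0.08). Neural crest and Schwann cell precursor genes had a median of 0.02 over 16 genes (adjusted p = 0.779; Dhh 0.22, SE 0.07; Cdh19 0.17, SE 0.09), skeletal muscle precursor genes -0.01 over 16 (0.789; Tnnt1 0.37, SE 0.19; Chrnd -0.08, SE 0.05) and matrix metalloproteinases and their inhibitors 0.02 over 18 (0.96; Adamts9 0.17, SE 0.07; Timp2 -0.12, SE 0.06). Erythroid genes had a median of 0.30, with all 9 higher (adjusted p = 0.0767; Klf1 0.37, SE 0.21; Hbb-bh1 0.34, SE 0.22). The erythroid list was called without wild-type C (median 0.59, adjusted p = 7.96e-10) and with array weights (0.0409), but with an estimated correlation in neither (adjusted p = 0.495 and 0.749). Its median was 0.041 without wild-type B, 0.13 without wild-type A and 0.14 without the array labelled knockout A. Klf1 was at 0.20 without wild-type A and 0.61 without wild-type C, and Hbb-bh1 at 0.15 without wild-type B and 0.59 without wild-type C. Macrophage genes had a median of 0.00 over 16 (0.66; Fcgr1 0.25, SE 0.07; Cd68 0.28, SE 0.14). Immediate early and heat shock genes had a median of 0.03 over 14 genes (0.416; Fos 0.24, SE 0.09; Jun 0.24, SE 0.15) and hypoxia and glycolysis genes 0.02 over 16 (0.907; Adm -0.31, SE 0.09; Pfkl -0.18, SE 0.06). With single arrays left out the medians of the dorsal root ganglion, neural crest, muscle, metalloproteinase, macrophage, immediate early and hypoxia lists all changed sign, within -0.048 and 0.095. Without the array labelled knockout C, Cdh19 was at 0.072, Tnnt1 at 0.14 and Fos at 0.14; Adamts9 was at 0.11 without knockout A, Chrnd at -0.046 and Cd68 at 0.42 without knockout B, and Jun at 0.12 without wild-type C. For the Slit and Robo, metalloproteinase, dorsal root ganglion, skeletal muscle, anterior Hox, macrophage and hypoxia lists, the median, the mean and the camera direction did not all have the same sign.

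Genes near Nkx2-9 on chromosome 12 had a median of 0.05 over the 27 measured members of the fixed list, with 21 higher and none past the test over all probe sets or over the list alone (camera adjusted p = 0.146; Foxa1 0.18, SE 0.05; Cfl2 -0.22, SE 0.07). This list was called without wild-type B (0.0333), but not with an estimated correlation (adjusted p = 0.838), and its median was 0.0177 without the array labelled knockout C and 0.0265 without wild-type C. Sex-linked genes differed between arrays of the same label. Xist stood at 4.56 and 4.91 in the arrays labelled knockout B and C and between -0.25 and 0.11 on the other 4 arrays. The Y-linked genes Kdm5d, Eif2s3y and Uty lay between -2.57 and -3.20 in those arrays and between -0.03 and 0.17 on the other 4. All 4 measured genes of this list passed over the list alone (adjusted p from 0.0463 to 0.0482 in limma), and the list was too short for camera.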

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

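The robust prior, the term for the 2 arrays with high Xist, the posterior Hox count and the estimated correlation under other settings were chosen after seeing the data. The planned brightness filter and the 2 priors with an intensity trend were not run because the centred values hold no levels, and signal over background could not be judged. Nkx2-9 stayed higher in the arrays labelled knockout and did not pass after adjustment under all 12 alternatives, from 0.01 to 0.27; its unadjusted p in limma ran from 0.012 with the replicate block, and 0.0431 without the array labelled knockout A, to 0.925. The count of probe sets past an adjusted p of 0.05 in limma was 0 except without the array labelled knockout A, where it was 5 (range 0 to 5 over the arrays left out): Xist, Kdm5d, Eif2s3y, Uty and a probe set without a single symbol, named after their values were seen. Without that array, the arrays labelled knockout all had high Xist. The 18 probe sets past the unadjusted p of 0.01 and 1.5-fold became 72 with the Xist term and 5 with the unequal-variance test, and 9 (without wild-type B) to 124 (without the array labelled knockout B) when arrays were left out. The letters A, B and C were treated as names: the deviations of same-letter arrays correlated at 0.165, 0.216 and 0.016, the last not over 0.1. The arrays of letters A and B each correlated best with their own letter, and those of letter C did not. With the letter as a replicate block the count was 43, the adjusted count 0 and the number of called lists 10, among them somatic motor neurons (adjusted p = 0.0386) and erythroid genes (0.0438), which were not called without it, nor with it at an estimated correlation (adjusted p = 0.727 for both). The block also raised the number of probe sets at an unadjusted p under 0.05 in limma from 1605 to 2552. The 8 called lists became 0 with an estimated correlation, also under every other setting and array left out, and 0 with fry, and with the preset correlation were 6 to 11 over the other alternatives. Candidates past their list alone were 1 with the Xist term (Tbx20, 0.56, SE 0.10, adjusted p = 0.0281, named after its value was seen), and 0 to 3 over the arrays left out, the 3 without knockout B. Posterior Hox genes past their list alone, 6 with all arrays, were 3 (without wild-type B) to 7 over the arrays left out, and 5 to 8 over the other alternatives. The 7 without knockout C and the 8 with the Xist term each include Hoxc5, which was higher (0.35 and 0.48); it was named after its values were seen. With the Xist term the neural progenitor list was called (adjusted p = 0.0487), but not with an estimated correlation (adjusted p = 0.911). Of the 85 genes named by the rule besides Nkx2-9, 26 moved by over 1.5 times or changed sign with the Xist term, 6 with quantile normalization, 3 with array weights and 6 to 18 over the arrays left out, the 18 without wild-type B and also without knockout C. The causes of these differences were not tested.

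The values that reversed had not passed a test, except Kdm5d, which had passed over its list alone, and the mesenchyme list, which had been called. With the Xist term, which by construction takes up sex-linked differences, Kdm5d was at 0.069 and the list medians were -0.0068 for Slit and Robo, -0.028 for metalloproteinases, -0.016 for basal lamina, 0.019 for dorsal root ganglion, -0.037 for neural crest, -0.041 for mesenchyme, 0.032 for muscle, -0.064 for vessels, -0.044 for immediate early genes and -0.019 for hypoxia. With array weights they were 0.0082 for Eph and ephrin, -0.0013 for metalloproteinases, 0.039 for dorsal root ganglion, 0.0059 for muscle and 0.014 for macrophages, and with quantile normalization 0.028 for dorsal root ganglion. Leaving out each array gave Robo3 from -0.030 to 0.17, Ntn1 from -0.078 to 0.13 and Isl1 from -0.21 to 0.12. The list medians then ran from -0.011 to 0.070 for Hedgehog, -0.087 to 0.016 for dorsal-exiting motor neurons, -0.031 to 0.051 for Slit and Robo, -0.084 to 0.027 for netrin and DCC and -0.043 to 0.019 for Eph and ephrin. They ran from -0.048 to 0.061 for metalloproteinases, -0.080 to 0.011 for dorsal cord, -0.0001 to 0.059 for dorsal root ganglion, -0.011 to 0.095 for neural crest and -0.029 to 0.17 for mesenchyme. The remaining ranges were -0.026 to 0.0085 for muscle, -0.055 to 0.17 for vessels, -0.035 to 0.065 for macrophages, -0.013 to 0.091 for neural progenitors, -0.034 to 0.11 for anterior Hox genes, -0.0091 to 0.093 for immediate early genes and -0.0086 to 0.036 for hypoxia. The causes were not tested.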

Other observations

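Of the tests in this part, those of sex, of surrounding tissue (with its scaling by SD) and of wild-type B were chosen after the result was seen, as were the rank correlation over paralog groups 1 to 9 and the count of posterior Hox genes over other splits; the correlation over all Hox genes and the other 3 counts over splits were set before their results.

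Beyond the groups, 2 single arrays stood apart in marker genes. The array labelled knockout C held connective tissue transcripts at high values, with Lum, a proteoglycan of connective tissue, at 3.31, and the mesenchymal transcription factor genes Foxd1, Foxc2 and Twist1 at 3.07, 3.01 and 2.32, all 4 named after their values were seen. Wild-type B was second highest for Lum (1.66), Foxc2 (1.21) and Twist1 (0.86), and had the lowest median of cell cycle genes (-0.56). Its median of erythroid genes was also the lowest (-0.46), but wild-type A lay close to it (-0.41). Among the 40 measured genes nearest to Nkx2-9, 20 on each side, 30 were higher and 10 lower in the arrays labelled knockout, with a median of 0.04; 0 passed an adjusted p in limma and 3 had an unadjusted p under 0.05.

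Posterior Hox genes were lower in the arrays labelled knockout, and 7 of the 17 measured had all 3 of those arrays below all 3 wild-type arrays. Surrounding tissue in knockout C is argued against as the whole cause, since without that array the list median was -0.292, with 14 of 17 lower. Sex stays open: with a term for the 2 high-Xist arrays the list median was -0.366 (camera adjusted p = 6.38e-06; adjusted p = 0.501 with an estimated correlation), but that value is read from knockout A alone, the array with the lowest median of this list (-0.32), with the spread taken from the other groups, and 1 array excludes nothing. A more anterior piece of cord in those arrays may contribute and stays open: over all 37 measured Hox genes, which are not independent, the rank correlation of log2 fold change with paralog group was -0.066 (permutation p = 0.697), while the -0.564 over groups 1 to 9 restates the pattern, because that range was picked afterwards and ends where the low genes end. Hox genes above group 9 had log2 fold changes between -0.11 and 0.11, so they can weaken the correlation over all Hox genes. Differences within a label had also been predicted for dissection level. The list medians spread over 0.211 within the wild type and 0.274 within the arrays labelled knockout. Single genes spread more. Hoxc8 stood at 3.56 in wild-type B, against -0.0072 in A and 0.27 in C. Hoxc6 stood at 1.44 in wild-type B, against 0.54 and 0.37, both genes picked after their values were seen. Hoxa5, Hoxb5, Hoxc5, Hoxb6, Hoxa10 and Hoxc10 were instead lowest in wild-type B among the wild type. Such spread can have other sources, so it does not decide the question. Genotype cannot be told apart from dissection level or sex, because the design holds no measure of level and no wild-type array with high Xist. Xist and the Y-linked genes already set knockout B and C apart from the other arrays. Embryos matched for sex and dissected by somite number would be needed to test these explanations.

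Mesenchyme and vessel genes were highest in knockout C. Of the 44 measured members of both lists, 34 (77.3%) were highest on that array, against 27.4% of all 19920 genes, since its values spread most widely (SD 0.191, against 0.0979 to 0.140 on the others). With each array divided by its SD, 33 of the 44 (75%) were highest there, against 14.1% of all genes. Before that division 73.9% of cell cycle, 66.7% of basal lamina and 62.5% of macrophage genes were highest there too. After it their shares were 17.4%, 58.3% and 25%. The members of a list are not independent, so no p is given. The neuron list had its lowest median there (-0.17). Adhering surrounding tissue in that sample is a candidate explanation that these values fit, tested on the array in which it was noticed; no biological explanation was tested.

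Cell cycle genes were higher in the arrays labelled knockout, although 0 of the 23 had the groups fully apart. Sex stays open: of the 2 high-Xist arrays knockout B (-0.11) lay below knockout A (0.18) and knockout C (0.26) above it, and with the term for those arrays, again read from knockout A alone, the list median was 0.405 (camera adjusted p = 4.9e-07; adjusted p = 0.911 with an estimated correlation). Wild-type B may carry much of the difference: without it the list median was 0.124, against 0.33, a value between the bounds set for its absence and its persistence. Genotype, sex and the state of that 1 sample cannot be told apart with 3 arrays a group.

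The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The count past an adjusted p was 0 in all 10 splits, the highest other being 0. The count past the unadjusted p and 1.5-fold was 18 in the real split, 3 splits gave as many, the real one included, and the highest other was 45, for knockout A, knockout C and wild-type C against the rest. The count of called lists was 8, 5 splits gave as many, the real one included, and the highest other was 10. Posterior Hox genes past the list alone were 6 in the real split and 0 in each of the other 9.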
